A study of Drosophila melanogaster with 3 samples.

How the data were processed

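Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Drosophila melanogaster embryos of mixed sex, collected 0 to 24 hours after egg laying. The flies carried a stable transgene for CG3995 with green fluorescent protein fused to its C terminus, and an antibody against the fluorescent protein recovered the bound chromatin. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. The 3 libraries were biological replicates of 1 group, and no second condition was among them. A control library was named for the peak caller in the submitters' notes, but its reads were not analysed here.

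The deposited files were peak lists in narrowPeak form on both dm6 and dm3, and no reads or coverage were used. For each build there were 5 lists. Each replicate had 1 list of regions that held peaks and background, called by the authors from that replicate's alignment with a control file, per the submitters' notes. A pooled list was called from the alignments of all 3 replicates together. A thresholded list held the regions kept by the irreproducible discovery rate procedure, which compares the ranks of regions between replicates. The aligner, the peak caller, their versions and the threshold of that procedure were not given in the sources used here. Each region of the deposited lists had a signal value, the authors' own measure of enrichment over the control file, and a −log10 q-value with 1 highest value shared by many regions. The signal scale differed between lists, so signal was used to rank, filter or compare regions within a list, and between lists only by rank. The read depth of each library was unknown, and no depth was inferred from the lists.

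All 4260 thresholded dm6 peaks were the 4260 strongest regions of the pooled list by signal, so the thresholded list was treated as a list called on pooled replicates. Comparisons between replicates used the same number of strongest regions of each replicate list. No line was shared between the lists of any pair of replicates. The thresholded list had 120 lines whose interval was used again with another summit, and overlapping intervals merged into 3979 regions. The thresholded list was analysed line by line, and 1 summit per merged region was tried as an alternative.

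Genes and start sites came from Ensembl release 115 (BDGP 6.54), and sequence from the RefSeq copy of the same assembly, whose chromosome arm lengths were those of dm6 (for example 23542271 bp for X). Only the arms 2L, 2R, 3L, 3R, 4 and X were used, with 18164 genes, 13945 of them protein-coding, and 23584 start sites. Annotated transposable elements were not counted as genes. No dm3 annotation was used, so dm3 lists gave only counts, overlaps and the share of peaks on X. Coordinates are 1-based dm6 positions.

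The 30 gene lists, 22 consensus sequences, the tests of the report's main comparisons and most alternatives were fixed before the data were examined. The comparisons by peak strength, of DRE positions around summits and of the closing section were not part of that plan. Of 369 gene symbols in the lists given by symbol, 366 were found, 12 of them through a synonym. A gene was called bound when a thresholded summit lay within 500 bp of 1 of its start sites. Each list was compared with all other protein-coding genes (RNA gene lists with all other genes) by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 30 lists. Summits were assigned in the order promoter (within 500 bp of a start), 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic. Shares of summits were compared with shares of sequenced bases by an exact binomial test, two-sided. Windows of 50 bp to each side of a summit were compared with a pair of windows of the same size centred 300 bp to either side, by Fisher's exact test with adjustment over the 22 sequences. The same test was run on all 32896 sequences of 8 bases, each counted together with its reverse complement. Overlap between replicates, at least 1 bp, was compared with 1000 random placements of the regions on their own chromosomes (one-sided permutation test). Intervals of shares are Wilson 95% intervals and cover counting error only. P-values over peaks, windows or genes do not measure the spread between embryo collections. For some results the same values from the strongest regions of each replicate are therefore given as mean ± SD with n = 3. Where no such value is printed, that spread is not shown.

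The genes named were set by a rule fixed beforehand. They were the genes nearest to the 20 thresholded peaks with the largest signal, up to 4 bound members with the largest signal from each list past the threshold, bound members of lists with fewer than 12 genes, CG3995 itself, and the 10 sequences of 8 bases with the smallest p among those enriched. Genes were given as neighbours of peaks, and the other genes with a start within 500 bp of the summit were named for the 20 strongest peaks and for some list members only. Many other list members named also had such a neighbour. One gene that the rule names is not reported here.

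The alternatives were the dm3 lists, a reciprocal overlap of 50%, summits within 100 bp, the 2130 strongest peaks or regions, peaks found among the strongest regions of all replicates, other promoter distances, other backgrounds and windows, and leaving out each replicate. Keeping 1 summit per merged region, giving each peak to the single nearest start, and leaving out replicates around the tagged gene were chosen after seeing the data.

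Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, with fixed random seeds. The code was tested on simulated data. The overlap counts were equal to those of bedtools 2.31.1 (473 and 473 regions by any overlap, 236 and 236 by reciprocal overlap). When 60% of ribosomal protein genes and random other genes were given peaks, the ribosomal list was called in 20 of 20 simulations and the other protein-coding lists in 3 of 520 tests. When 5% of random windows were given the sequence TATCGATA, it was called in 20 of 20 simulations and the other sequences in 0 of 420 tests. Uniformly placed summits gave a promoter share of 13.6%, against 13.6% of bases.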

Results

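Binding of CG3995 to chromatin was mapped by ChIP-seq in whole Drosophila embryos aged 0 to 24 hours. CG3995, named bdwf in the annotation (FBgn0038472), lies on the minus strand of chromosome 3R from 17041896 to 17043136. The protein was recovered through a fluorescent protein tag in 3 biological replicates, which formed a single group with no second condition. The design therefore asked where the tagged protein was found and how well the replicates matched. The replicate lists held 30000, 28051 and 24171 regions (27407 ± 2967, SD, n = 3), and replicate 1 held 30000 on dm3 as well. No limit on list length was stated, but the repeated round number has the form of one, so the count of replicate 1 and the mean were read as lower limits. These lists included background regions, and the thresholded list kept 4260 peaks with a most common width of 416 bp. Depth per library was unknown. No control immunoprecipitation was analysed here, so a bound promoter below means one with a thresholded peak, which does not separate binding of the tagged protein from a general recovery of active promoters. Signal values are the peak caller's own, without a unit, and are compared here within the thresholded list, and between replicates only by rank.

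The strongest peaks stood close to the starts of genes, and no shared function was tested among those genes. The peak with the largest signal (50371) lay on 3L from 16587723 to 16589152, with its summit at 16588366 in intergenic sequence, 109 bp upstream of l(3)73Ah (FBgn0002283), which encodes a RING-finger protein related to a Polycomb group subunit. The 41 bases around that summit, 16588346 to 16588386, read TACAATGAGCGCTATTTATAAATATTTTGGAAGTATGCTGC. The next peak (36677, 2L from 7799250 to 7800621) had its summit in the 5' UTR of Herp (FBgn0031950), a gene of the endoplasmic reticulum stress response, and r2d2, a gene of the small RNA pathway, also had a start within 500 bp. The third lay 78 bp upstream of CG10628 (FBgn0032818; signal 26306), with Dus3 nearby. The fourth lay 117 bp upstream of Top2 (FBgn0284220; 25527), which encodes DNA topoisomerase II, and the fifth 54 bp upstream of P58IPK (FBgn0037718; 24726), which encodes a co-chaperone of the endoplasmic reticulum. These 5 peaks held ranks 1 to 6 in every replicate list.

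The other 15 of the 20 strongest peaks had signals from 18034 to 22960. Among them were the mitochondrial genes UQCR-C2 of respiratory complex III (22105, summit in its 5' UTR), ND-MWFE of complex I (18137), Echs1 of fatty acid oxidation (21046) and MagR, an iron-sulphur protein (19209). Genes for chromosome organisation were Mau2, a cohesin loader (20829), Cap-H2, a condensin II subunit (18739), and Sfmbt, a Polycomb group protein (18242). The remaining peaks had CG5510, CG5013, CG13096, CG11247, Usp12-46, CG31064, TM9SF3 and CG8319 as the gene with the nearest start. Polr2H, which encodes a subunit of RNA polymerases, shared the peak of CG11247, and PolA2, which encodes a subunit of DNA polymerase alpha, shared that of CG31064. Further genes with a start within 500 bp were IKKbeta and lncRNA:CR45212 at the CG5013 peak, asRNA:CR44367 at Echs1, Spn88Eb at Mau2, CG7029 and rumi at Usp12-46, CG12379 at MagR, MED7 at Cap-H2, CG5439 at Sfmbt, mthl2 at TM9SF3, TppII at ND-MWFE and CG9427 at CG8319. The ND-MWFE summit lay in an intron of TppII and the Cap-H2 summit in an exon of asRNA:CR45016. All 20 summits lay within 500 bp of a start and 19 within 200 bp. Each of the 20 ranked among the strongest 27 regions of each replicate. The median signal over all 4260 thresholded peaks was 227, so the l(3)73Ah peak was 222 times the median.

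Promoters held most of the peaks. Of 4260 thresholded summits, 3199 (75.1%, interval 73.8 to 76.4%) lay within 500 bp of a start site, where 13.6% of bases lie, a 5.53-fold excess. The strongest regions of the replicates gave 74.8% ± 1.51 (SD, n = 3). Introns held 725 summits (17.0%, against 39.5% of bases) and intergenic sequence 240 (5.63%, against 27.1%). The classes exclude each other, so the promoter excess by itself lowers the shares of all the others. Introns held 725 of the 1061 summits outside promoters, so their low share does not show that introns were avoided. Coding exons held 20 summits (0.469%, against 13.7% of bases), 5' UTRs 19, 3' UTRs 43 and other exons 14. In an exact binomial test of the upper tail only, the log10 of p for the promoter share was -1805. In the two-sided exact binomial test p was 1.01e-235 for the low share of coding exons. The median promoter summit was 59 bp upstream of the start, the quartiles lay at -121 and -15 bp, and 80.1% of promoter summits were upstream.

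**Figure D1:**
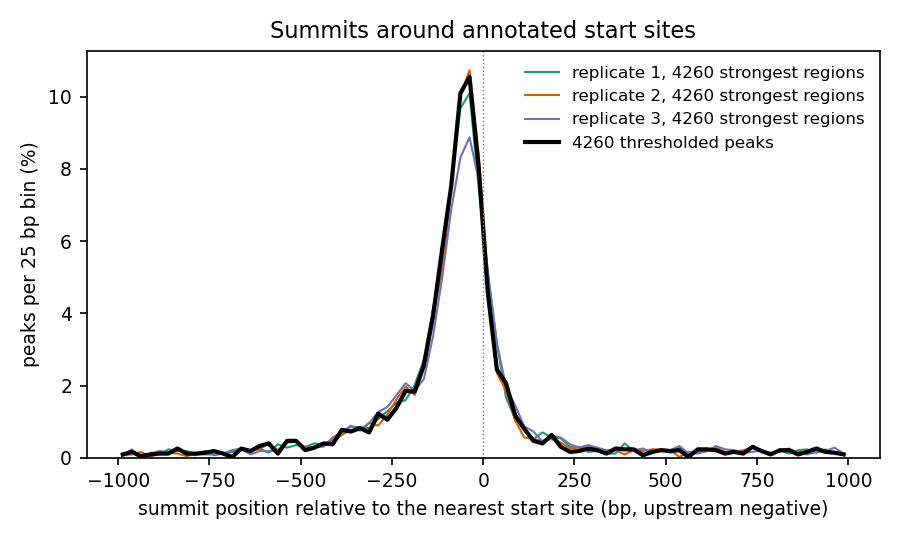
Position of summits relative to the nearest annotated start site in bp (horizontal axis, upstream negative) against the percentage of peaks per 25 bp bin (vertical axis), for the thresholded peaks (black) and the 4260 strongest regions of each replicate (colours). The peak of every curve lies just upstream of the start, with median promoter summits 57 to 60 bp upstream.

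Peak strength went with promoter location. Of the 852 strongest peaks 86.5% (84.0 to 88.6%) were at promoters, and of the 852 weakest 64.0% (60.7 to 67.1%; Fisher's exact test, two-sided, p = 1.56e-27). The classes between had 79.7%, 74.5% and 70.8%.

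Genes for ribosomal proteins, respiration and the proteasome were bound more often than other protein-coding genes. Gap and pair-rule, dorsal-ventral, cuticle protein and chemoreceptor genes were bound less often, as were histone, tRNA, snRNA and snoRNA genes. Among 13945 protein-coding genes 3936 (28.2%) were bound, and the strongest regions of the replicates gave 3827 ± 137 (SD, n = 3). Of 30 lists, 8 were bound more often and 8 less often than their background at an adjusted p under 0.05. Those higher lists were called the same way from the strongest regions of all 3 replicates.

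Cytosolic ribosomal protein genes stood out, with 75 of 86 bound (87.2%, against 27.9% of other genes; odds ratio 17.7, adjusted exact p = 8.08e-29), and the replicates gave 85.7% ± 3.36 (SD, n = 3). Bound members included RpL36A (965), RpS3A (965, on chromosome 4) and RpS27 (846), and these peaks were far weaker than the 20 strongest. Mitochondrial ribosomal protein genes had 42 of 73 bound (57.5%, adjusted exact p = 6.68e-07), led by mRpL37 (10414), mRpL42 (3757), mRpL9 (3596) and mRpS23 (3505). Oxidative phosphorylation genes had 38 of 71 bound (53.5%, adjusted exact p = 2.89e-05), with COX7B (3506) and ND-30 (2929) after UQCR-C2 and ND-MWFE; the ND-30 summit lay 437 bp upstream of its start in the 5' UTR of CG15812. Proteasome genes had 20 of 32 bound (62.5%, adjusted exact p = 0.000262), led by the regulatory particle genes Rpt2 (15408) and Rpn1 (11569), and by Prosalpha4 (4341) and Prosalpha7 (4018) of the core particle.

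Translation factor genes had 27 of 53 bound (50.9%, adjusted exact p = 0.00159), with eIF3c (16502), eRF3 (8587), eIF3m (5311) and eIF4G1 (5255). Splicing genes had 17 of 27 (63.0%, adjusted exact p = 0.000909), with SmE (991), Prp19 (751), SNRPG (460) and SmD2 (343). DNA replication genes had 17 of 33 (51.5%, adjusted exact p = 0.012), with PolA2 (19230), the helicase subunit genes Mcm7 (2173) and Mcm5 (570), and Psf1 (796, summit in the 5' UTR of Sac1). Insulator and architectural protein genes had 11 of 16 bound (68.8%, adjusted exact p = 0.00222), with mod(mdg4) (12185), Chro (955), Cp190 (574) and Dref (425), whose product binds the DNA replication-related element (DRE). The summit at Dref lay 26 bp upstream of its start and also within 500 bp of RpL13. The DNA replication call ended in 5 alternatives, among them a promoter distance of 200 bp (36.4% bound, adjusted exact p = 0.111) and the 2130 strongest peaks (27.3%, adjusted exact p = 0.224). In those 2130 peaks the oxidative phosphorylation, proteasome and splicing calls ended as well (adjusted exact p = 0.224, 0.0897 and 0.171), and the mitochondrial ribosomal call ended when genes were taken by nearest start at any distance (31.5%, 0.223).

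**Figure D2:**
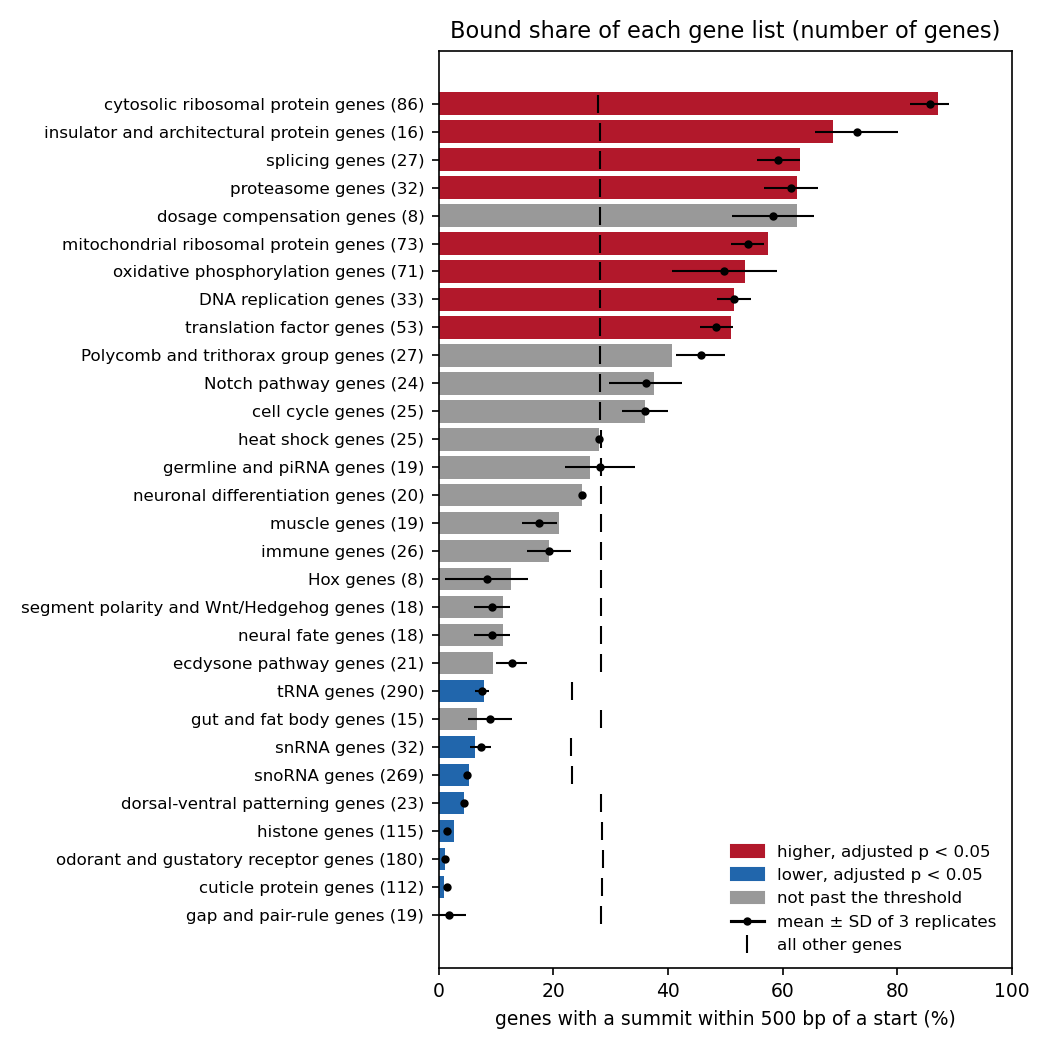
Percentage of genes with a summit within 500 bp of a start (horizontal axis) for each of 30 gene lists, with the number of genes in brackets. Bars are thresholded peaks, points and error bars the mean ± SD of the strongest regions of 3 replicates, and vertical ticks the share among all other genes; the ribosomal protein bar reaches 87.2%.

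Gap and pair-rule genes had no promoter peaks. None of the 19 gap and pair-rule genes had a thresholded summit within 500 bp of a start (28.3% of other genes did, adjusted exact p = 0.00784), and of 23 dorsal-ventral patterning genes only cact, an inhibitor of nuclear import of Dorsal, had 1 (signal 249, adjusted exact p = 0.0178). Among 112 cuticle protein genes only Lcp9 was bound (adjusted exact p = 3.48e-14), by a summit 474 bp upstream of its start that lay nearer to CG3594. Among 180 odorant and gustatory receptor genes, Gr97a (227) and Ir31a (145) were bound (adjusted exact p = 5.21e-22). Of 115 histone genes 3 were bound (adjusted exact p = 3.73e-12), and these were His2Av (325), His3.3B (131.5) and His4r (211), which lie outside the replication-dependent histone gene cluster. The low histone count is uncertain, since against genes near any region the call ended and turned round (75% of 4 genes, against 37.2%; adjusted exact p = 0.235), and since the cluster's genes are near-identical copies whose reads cannot be placed uniquely.

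Small RNA genes were also low, by distance to their annotated starts. Whether those starts are promoters was not examined, so the low shares do not show that promoters of small RNA genes were avoided. Of 290 tRNA genes 23 were bound (7.93%, against 23.3% of other genes, adjusted exact p = 5.7e-11), led by tRNA:Trp-CCA-2-2 (1285), the neighbouring tRNA:Ser-TGA-1-1 and tRNA:Ser-TGA-2-1 under 1 peak (744) and tRNA:Asn-GTT-1-5 (655). Of 269 snoRNA genes 14 were bound (5.204%, adjusted exact p = 1.96e-14). The strongest of them was snoRNA:Me28S-C2645a (14328), whose peak is shared with its host gene Uhg3, followed by snoRNA:Psi28S-2949 and snoRNA:Or-aca5 beside Uhg4 (430) and snoRNA:Psi18S-1275 beside RpS29 (376). Of 32 snRNA genes snRNA:7SKa (292) and snRNA:U4:39B (239) were bound (adjusted exact p = 0.0378). The gap and pair-rule call held in the strongest regions of 2 of 3 replicates. The snRNA call held in those of 1 replicate and ended without any 1 replicate (adjusted exact p from 0.127 to 0.160) and in most other alternatives, and the dorsal-ventral call ended without replicate 1 (adjusted exact p = 0.0848) or replicate 2 (0.0856). The dorsal-ventral call also ended in peaks found in all replicates, in the 2130 strongest peaks, at 200 and 1000 bp, and with both rules of nearest start (adjusted exact p from 0.079 to 1). The snoRNA call ended at a promoter distance of 1000 bp (23.8% bound, adjusted exact p = 0.476), and the gap and pair-rule call ended when genes were taken by nearest start at any distance (21.1%, adjusted exact p = 1), in the 2130 strongest peaks (0.161) and against genes near any region (0.0629).

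The other 14 lists did not pass the adjusted test. Dosage compensation genes had 5 of 8 bound (adjusted exact p = 0.0798), namely msl-1 (442), mof (208), msl-2 (183), lncRNA:roX1 (174) and Clamp (158). Of 8 Hox genes lab was bound (signal 131.5, summit 12 bp upstream), by a peak that ranked 4173, 8651 and 2980 in replicates 1, 2 and 3. It was thus outside the 4260 strongest regions of replicate 2. Polycomb and trithorax group genes had 11 of 27, Notch pathway genes 9 of 24, cell cycle genes 9 of 25, heat shock genes 7 of 25, germline and piRNA genes 5 of 19, neuronal differentiation genes 5 of 20, immune genes 5 of 26 and muscle genes 4 of 19. Segment polarity and neural fate genes each had 2 of 18, ecdysone pathway genes 2 of 21, and gut and fat body genes 1 of 15. Among these lists 3 passed in some alternatives. Dosage compensation genes passed without replicate 3, at 200 bp and by both rules of nearest start (adjusted exact p from 0.0264 to 0.0483; up to 1 in the others). Polycomb and trithorax group genes passed by nearest start at any distance (63.0%, adjusted exact p = 5.87e-05) and by single nearest start (0.0312), and cell cycle genes by the former (48%, 0.0226).

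Summits carried the DRE, a promoter sequence of genes for proliferation and basic metabolism, and the core of Motif 1, another element of broadly active promoters. The DRE sequence TATCGATA was found within 50 bp of 299 of 4260 summits (7.02%), against 0.892% of flanking windows, a ratio of 7.87 (6.13 to 10.1; Fisher's exact test, two-sided, adjusted exact p = 5.85e-77). In the strongest regions of the replicates 6.93% ± 0.433 (SD, n = 3) had it. Motif 1 (GGTCACAC) was found at 145 summits (3.40%, against 0.739%; ratio 4.60, adjusted exact p = 7.32e-26; replicates 3.41% ± 0.434). The GAGA sequence, bound by GAF at many developmental promoters, was lower at summits (0.869%, against 2.72%; ratio 0.319, adjusted exact p = 1.37e-12), as was a CA repeat (1.10%, against 3.68%; ratio 0.299, adjusted exact p = 4.32e-18). DRE sites within 200 bp of a summit gathered near its centre, with 183 of 696 (26.3%) within 25 bp, where an even spread gives 12.7% (exact binomial p = 4.51e-22).

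Insulator sequences were rarer. The CTCF core was at 34 summits (0.798%, against 0.270%; ratio 2.96, adjusted exact p = 0.000238), and the Su(Hw) core at 40 (0.939%, against 0.446%; ratio 2.11, adjusted exact p = 0.00334). The CTCF call ended without replicate 1 (ratio 1.90, adjusted exact p = 0.109) in peaks found in all replicates (ratio 2, adjusted exact p = 0.075) and in the 2130 strongest peaks (ratio 1.13), where the Su(Hw) call ended too (ratio 1.73, adjusted exact p = 0.320). A homeodomain core (7.61%, against 5.92%; ratio 1.29, adjusted exact p = 0.00107) and the TATA box (1.88%, against 1.19%; ratio 1.58, adjusted exact p = 0.00599) were also higher than at flanks. Against windows at the same offset from unbound starts the TATA box turned round, to a ratio of 0.407 (adjusted exact p = 4.42e-10), while the DRE kept a ratio of 4.38 (3.37 to 5.70) and Motif 1 of 3.33. The CTCF, Su(Hw) and homeodomain calls ended against those windows (adjusted exact p = 0.118, 0.424 and 0.117), and the homeodomain call also in the 2130 strongest peaks (ratio 1.23, 0.128). The TCT initiator of ribosomal protein promoters (ratio 0.834, adjusted exact p = 0.00528) and a run of A (0.811, adjusted exact p = 0.0224) were lower than at flanks, and neither kept its direction in every alternative. Against unbound starts GAGA stayed lower (ratio 0.333, adjusted exact p = 1.16e-06), while the CA repeat had a ratio of 0.681 and no longer passed the test (adjusted exact p = 0.255). The E-box, Zelda, initiator, Pho, Mef2, E2F, STAT, heat shock, Ets, CRE, GATA and Pol III B box sequences did not pass the adjusted test. In alternatives GATA passed as higher in peaks found in all replicates, without replicate 1 and in wider windows (ratios 1.27 to 1.35), and the initiator as lower against unbound starts (0.543).

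**Figure D3:**
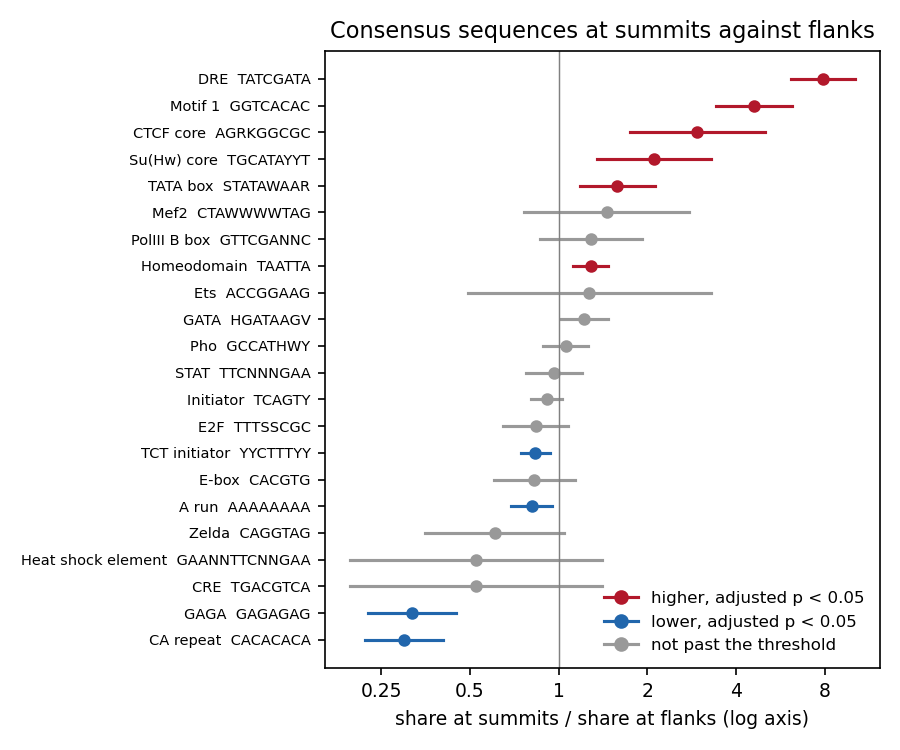
Ratio of the share of summit windows to the share of flanking windows with each of 22 consensus sequences (horizontal axis, log scale, no unit; points with 95% intervals), coloured by the adjusted two-sided Fisher test. The DRE (7.87) and Motif 1 (4.60) lie highest, and GAGA (0.319) and the CA repeat (0.299) lowest.

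Without any sequence fixed beforehand, the search over 32896 sequences of 8 bases had the DRE and Motif 1 at its top. Of these sequences, 779 were higher and 465 lower at summits after adjustment. Among those higher, 107 held CGATA and 94 held GTCAC, or their complements, and most held neither. The smallest p belonged to ATCGATAG (6.97%, against 0.798% of flanks; ratio 8.73, adjusted exact p = 2.55e-77). It was followed by TATCGATA, ACTATCGA (ratio 10.3), ATCGATAA (6.19), ATATCGAT (6.05), AACTATCG (9.68), CATCGATA (7.23), AATCGATA (4.21) and GCTATCGA (5.06), all overlapping the DRE. The tenth, GGTCACAC, was the Motif 1 core itself. The DRE was also tied to peak strength, with 11.5% (9.53 to 13.8%) of the 852 strongest summits and 3.76% (2.67 to 5.25%) of the 852 weakest (Fisher's exact test, p = 1.41e-09). For Motif 1 the shares were 3.76% and 2.82% (exact p = 0.342).

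**Figure D4:**
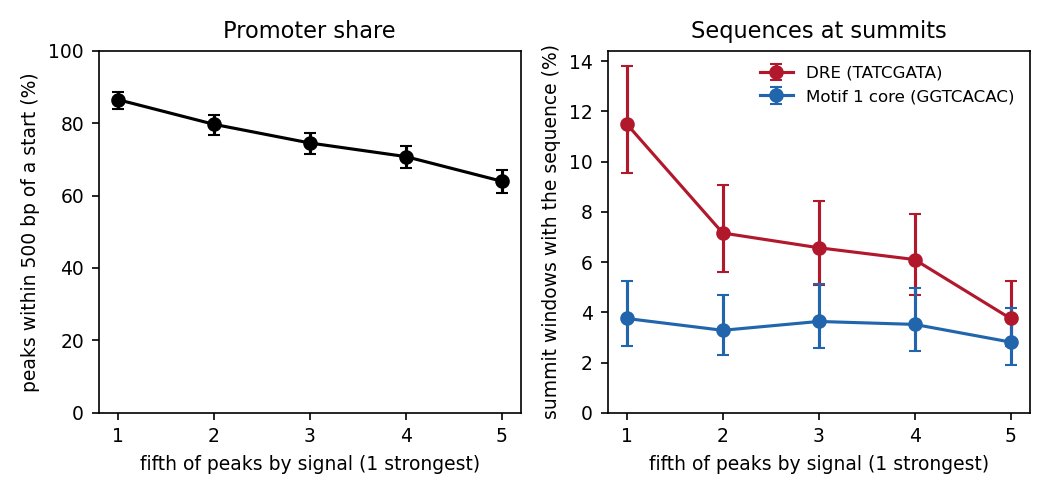
Peaks ranked by signal in 5 classes of 852 (horizontal axis, strongest first) against the percentage within 500 bp of a start (left) and the percentage of summits with the DRE or the Motif 1 core within 50 bp (right), with Wilson 95% intervals. The promoter share falls from 86.5% to 64.0% and the DRE share from 11.5% to 3.76%.

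Peaks were spread over the large arms in proportion to their length. On X lay 754 of 4206 peaks of the 5 large arms (17.9%, 16.8 to 19.1%), against 17.7% of bases (exact binomial test, two-sided, p = 0.747), and the replicates gave 17.7% ± 0.245 (SD, n = 3). Against the 16.7% of start sites on X the share was slightly higher (exact p = 0.0332), but this did not hold without any 1 replicate (p from 0.0843 to 0.273). Chromosome 4 had 54 peaks, or 40.6 per Mb, against 30.4 to 32.7 on the other arms, and 53.8% of its protein-coding genes were bound.

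Most of the same places were found in each embryo collection. Among the 4260 strongest regions of each replicate, 84.7% were shared between replicates 1 and 2, 80.7% between 1 and 3, and 79.4% between 2 and 3 (81.6% ± 2.76, SD over pairs), against 2.48% for random placement. The permutation p was 0.001 for each pair, the smallest that 1000 placements can give. Placement was uniform along each chromosome, so the test does not show agreement beyond a shared preference for promoters. Signal in overlapping regions had a Spearman correlation across regions of 0.673, 0.652 and 0.666 for the same pairs, and regions are not independent replicates. Of the thresholded peaks 3107 (72.9%, 71.6 to 74.2%) lay among the strongest regions of all 3 replicates, 821 in 2 of them, 318 in 1 and 14 in none. All of the 852 strongest peaks lay among the 4260 strongest regions of each replicate, against 16.7% of the 852 weakest. In the full lists 98.9% of thresholded peaks overlapped a region of every replicate. The thresholded list was called on these same replicates, so high shares of its peaks in them are not independent evidence.

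At the tagged gene itself, a peak of signal 1377 (rank 326) covered 3R from 17043360 to 17043766. Its summit at 17043565 lay 429 bp upstream of the bdwf start at 17043136, and 1 bp from the start of the neighbouring Patr-1, a gene of messenger RNA decay, in whose 5' UTR it fell. The 41 bases around the summit, 17043545 to 17043585, read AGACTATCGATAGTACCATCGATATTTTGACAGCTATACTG and contained the DRE sequence TATCGATA. The peak ranked 331, 358 and 310 in replicates 1, 2 and 3. A weaker thresholded peak (142) lay near the start of Trm7-32. It ranked 3413, 3419 and 12411 in replicates 1, 2 and 3, so it was outside the strongest regions of replicate 3. Within 20 kb of bdwf the replicate lists held 16, 23 and 11 regions, which put the locus at percentiles 66.8, 95.1 and 54.9 among windows of the same size around 3420 other genes of the arm (72.3 ± 20.6, SD, n = 3). Among the strongest regions only, 2 lay there in each replicate and the percentile was 47.9 ± 0.458, but within 50 kb it was 86.8 ± 7.74, with 10, 11 and 8 strongest regions against a median of 5. For all regions the percentile within 50 kb was 91.0 ± 7.64. The flies carried a tagged copy of CG3995, and extra copies of its locus can add signal there. This was not tested, so signal at this locus cannot be taken as binding alone.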

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

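One set of peaks lay outside the comparisons of the report and exceeded the 3 counts that a count of 0 allows. On dm3, 14 of 4086 thresholded peaks were on sequences other than the 6 arms, with 8 on 3LHet, 3 on 2RHet, 2 on XHet and 1 on 3RHet, which hold heterochromatin in that build. That limit only singled the peaks out and says nothing of their cause. No control sample was analysed here to set a level, genes on those sequences were not analysed here, and no biological explanation was tested.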

How the results depend on the processing

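The test with 1 summit per merged region, that with the single nearest start and that without each replicate at the tagged gene were chosen after seeing the data. Of 355 alternative values, 73 of main results stayed on the same side of their test or within their spread, 21 moved beyond it and 5 lost their call. Of the values of single lists and sequences 208 stayed, 44 lost their call and 4 changed direction. The promoter share (62.9 to 82.4%), the excess overlap of replicates (71.9 to 85.4%) and the X share against bases kept their result in every alternative. The X share against start sites lost its p in the 2130 strongest peaks (17.3%), in peaks found in all replicates (17.5%) and without each replicate (17.4 to 17.8%). With the 2130 strongest peaks, 4 lists were higher and 5 lower, 3 sequences and 360 8-base sequences were higher, 77.4% of peaks were in all replicates and the rank correlation was 0.864. That setting has fewer peaks per list and window set. The lists lower were also 5 at 1000 bp and 5 by nearest start. With a reciprocal overlap 56.0% of peaks were in all replicates (correlation 0.692), with summits within 100 bp 64.5% (0.774), and without 1 replicate 76.9 to 82.8%, where only 2 replicates have to match (0.652 to 0.673). Windows of 100 bp to each side gave 1495 higher 8-base sequences and 2 lower consensus sequences. Windows at unbound starts gave 2 higher consensus sequences and 188 of 8 bases. With the strongest regions the tagged gene's percentile was 47.9, and 86.8 within 50 kb. Those changing direction were histone genes against genes near any region (75% of 4 genes), the A run in wider windows (1.09), and the TATA box (0.407) and TCT initiator (1.02) at unbound starts. Unless stated, the cause was not tested. No paired analysis was possible because the samples form 1 group. Read depth is unknown, so weak regions missing from a replicate cannot be told from regions not sampled.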

Other observations

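The tests of neighbouring starts, of gaps between replicate regions and of AGTCAC in the strongest peaks were chosen after the result was seen. The other tests were set before theirs, but that of AGTCAC in weaker summits used a sequence already picked from these peaks. A short sequence, which shares GTCAC with the Motif 1 core, marked the strongest peaks. AGTCAC, picked after its values were seen, was within 50 bp of 92 of the 250 strongest summits (36.8%, 31.1 to 42.9%) and of 11 of the 20 strongest, against 3.12% of flanks. The other 4010 summits had it in 9.05%, so the ratio of the strongest to the rest was 4.07 (3.36 to 4.91). The weaker summits still exceeded flanks by a ratio of 2.90 (2.49 to 3.38). The DRE was at 2 and the full Motif 1 core at 1 of the 20 strongest summits. AGTCAC may be part of a sequence tied to the strongest binding of bdwf, a hypothesis found and tested on the same peaks.

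Bound genes often faced a neighbour. Of 3936 bound protein-coding genes 66.0% had a start on the opposite strand within 1000 bp upstream, against 24.5% of 10009 unbound genes (odds ratio 5.96). A peak between neighbouring starts can count for both genes, so each peak was also given to its nearest start only. Of the 2798 protein-coding genes reached in this way 54.5% had such a start. The share was 31.6% among the 11147 other genes, bound ones among them (odds ratio 2.59, Fisher's exact p = 9.63e-109). Away from promoters the DRE was rare, at 10 of 1061 summits (0.94%, against 0.094% of flanks). Its ratio to flanks was 10 (2.20 to 45.6), but this rested on very few windows. The CTCF core was at 16 of those 1061 summits (1.51%, against 0.283% of flanks), and Motif 1 at 2. Among protein-coding genes with the DRE near a start, 780 of 1336 were bound (58.4%), against 25.03% without it. With Motif 1 50.3% were bound, against 26.2% without, with a TATA box 18.4%, against 29.5%, and with the initiator 23.8%, against 31.5%. With GAGA near a start 30.0% were bound, against 28.1% without (odds ratio 1.10, exact p = 0.143), so genes with it anywhere in that stretch were not bound less often. At promoter summits themselves it was rarer than at the same offset from unbound starts (0.813%, against 2.44%). Only 14 summits (0.329%) fell in annotated transposable elements, which make up 5.94% of bases (exact binomial p = 1.28e-90), and reads from repeated copies may have been left unplaced.

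The higher binding of ribosomal protein, respiration, proteasome and other housekeeping lists was weighed against 3 technical explanations. GC content is argued against: all 8 lists kept a Mantel-Haenszel odds ratio whose interval lay above 1 within 10 classes of GC, and bound promoters had a median GC of 40.3% against 41.9%. Counting peaks for both of 2 neighbouring starts was not the whole cause for 7 lists, whose lowest odds ratio with the single nearest start was 1.84, while for DNA replication genes (2.00, adjusted exact p = 0.130) with 33 genes it cannot be told apart. Signal that follows transcription stays open. Ribosomal protein peaks had a median percentile of 59.7 (52.9 to 67.4) among promoter peaks and a median rank of 1537 of 4260, both above the middle. Yet 425 peaks were stronger than all of theirs. Ribosomal protein genes only stood in for highly transcribed genes, and no transcription level was measured. General recovery of open, active promoters was not tested, since no control immunoprecipitation was analysed here, and it stays open.

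The DRE at summits was weighed in the same way. Promoter composition was argued against by the ratio of 4.38 to windows at unbound starts, and repeated summits by a ratio of 9.42 with 1 summit per merged region. The sequence alone was not enough for a peak: 8 of 2160 DRE sites beyond 1000 bp of any start had a summit within 100 bp (0.370%), against 505 of 1557 near starts (32.4%), a ratio of 0.0114 (0.0057 to 0.0229). Random positions had a summit that near in 0.148% far from starts and 3.74% near them, so promoter location accounts for part of that ratio, and far DRE sites lay above random positions. No biological explanation was tested.

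Replicate 3 shared fewer strong regions with the others. A noisier weak tail as the only cause was argued against. Among the 1000 strongest regions the pairs with replicate 3 (86.7 and 87.65%) were under the other pair (91.4%), the lower by 4.70 percentage points. The gap was wider among the 16000 strongest regions (60.7 and 62.6%, against 69.0%), so a noisier tail may add to it. Summits of overlapping regions were 20 (19 to 22) and 22 (20 to 23) bp apart at the median in pairs with replicate 3, against 16 (15 to 17) in the other, so placement was slightly less exact. As the whole cause of the missing overlaps it was argued against: with gaps of up to 200 bp allowed between regions, the higher pair with replicate 3 (81.2%) still lay 3.87 percentage points (2.82 to 4.99) under the other (85.1%). Depth was unknown and stays open.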
